A study of Mus musculus with 8 samples.

How the data were processed

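RNA from pancreatic islets of 5-week-old C57BL/6 mice was sequenced in 8 libraries, 4 labelled TG and 4 labelled WT, and each library has its own table of read counts per Ensembl mouse gene. The deposited counts are whole numbers that were not normalized. STAR 2.7.10a, HTSeq 0.11.3 and the genome build mm39 are named in the submitters' processing notes, and the strand setting is not given in the sources used here. Each table ends in 5 entries for reads given to no gene. Reads outside any gene made up 25.3% to 31.5% of each table's total and ambiguous reads 3.74% to 4.36%, the other 3 entries were 0, and all 5 were left out of library sizes and tests. Groups and replicate numbers were taken from the sample labels. No pair of libraries of a group agreed within sampling noise, with a chi-square per gene between 16.5 and 58.9.

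Gene symbols, GC content and the order of neighbouring genes came from a mouse annotation of an earlier genome build, so no coordinates are given. It gave a symbol to 52081 of 55414 gene identifiers and GC content to 20414 of the tested genes. Where identifiers shared a symbol, the one with the most counts kept it. The other 68 kept only their identifier and entered no gene list.

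Genes with low counts were removed with edgeR's filterByExpr at a minimum count of 10, which left 20509 genes. Library sizes were scaled by TMM. Groups were compared with the quasi-likelihood test of edgeR 4.0.16 (robust, two-sided) in R 4.3.3 with group as the only term, and p-values were adjusted by the Benjamini-Hochberg method. Adjusted p-values of single genes come from this edgeR test, and a gene was called at an adjusted p under 0.05. Gene lists were tested with camera from limma 3.58.1 at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 29 lists that held at least 5 tested genes and were not a check of the animals. In all 31 lists with 646 entries were fixed, and no gene is in more than 1 list. Shares of counts were compared with exact permutation tests over 70 arrangements, whose smallest two-sided p is 0.0286. Counts per library are given as CPM on effective library sizes, except those of sex-linked genes and shares, which use gene counts.

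The genes named are Atf4 and Pde4d, the 10 genes with the largest rise and the 10 with the largest fall among called genes with a mean of at least 5 CPM and no overlap between groups (leaving out unnamed, clone-based and pseudogene symbols), up to 4 members of each list with the lowest adjusted p, the tested phosphodiesterase and incretin genes, Ins1, Ins2, Gcg, Sst and Ppy, and sex-linked genes. Some genes that this rule selects are not reported here, though they stay in the tests and list counts. The grouping, the tests, the lists, this rule and the alternative settings listed next were fixed before the data were examined. They were DESeq2 1.42.0, limma-voom, median-of-ratios and upper-quartile scaling, the 50 most abundant genes left out of the scaling, no filter, a filter of 1 CPM in 4 libraries, GC offsets, the replicate number as a block with and without GC offsets, the acinar list as a covariate, an estimated correlation and fry for lists, other denominators for shares, and each library left out in turn. The mean log2 CPM of the endothelial and the stellate, fibroblast and mural lists as a covariate was added after the data had been seen.

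The smallest library held 16521087 gene counts, in which 3 counts, the limit that a count of 0 allows, equal 0.182 CPM, and the largest held 22499999, where they equal 0.133 CPM. Intervals for shares are 95% Wilson intervals, and intervals and limits cover counting error only. The edgeR step was tested on simulated data drawn for the TG against WT comparison over 20509 genes, 10 times with 200 changed genes each, of which between 19562 and 19656 genes were tested. It recovered 22.1% of genes changed 1.5-fold, 51.9% of those changed 2-fold and 78.9% of those changed 4-fold, and 89 of 1106 calls (8.05%) were false. This false share is above the level of 0.05 that the adjustment aims at. Of 20 random lists camera called 0. Genes of a random list need not move together, whereas estimated correlations of the 29 tested lists ran from −0.044 to 0.856. This check therefore cannot show whether the preset correlation is too low for lists whose genes move together. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.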

Results

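Gene expression was measured by RNA sequencing in pancreatic islets from C57BL/6 mice at 5 weeks of age. Islets are the endocrine clusters of the pancreas, and most of their cells in the mouse are insulin-secreting beta cells. The 8 libraries fall into 2 groups of 4. By the labels, every mouse carried an ATF4 transgene in the heterozygous state. The group called TG here also carried Ins2 cre, a Cre recombinase driver named after the insulin 2 gene, and the group called WT did not. The title of the series names endoplasmic reticulum stress, Pde4d expression mediated by ATF4, and the response of islets to incretins, so the comparison asks which transcripts differ when the Cre driver is present. The libraries held between 16521087 and 22499999 counts assigned to genes, and between 31088 and 39510 genes had at least 1 count. Nothing in the labels says whether the 4 samples of a group came from separate animals, and p-values measure only the spread between these samples, which can be technical. The Y-linked gene Ddx3y lay between 144 and 192 CPM (counts scaled to library size) in the 8 libraries and Xist did not exceed 1.45 CPM.

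Atf4, the transcription factor that carries the integrated stress response, had lower counts in the TG-labelled libraries. Transcripts of the transgene may not be counted under Atf4, so these counts cannot check the labels. Atf4 (ENSMUSG00000042406) measured 261 ± 19.8 CPM (SD, n = 4) in the TG-labelled libraries and 352 ± 21.1 CPM (SD, n = 4) in the WT-labelled libraries, 1.35-fold lower in the former. The log2 fold change was −0.43 (SE 0.085, adjusted p = 0.00226, edgeR quasi-likelihood test, two-sided), and the groups did not overlap, with 234 to 278 CPM against 326 to 378 CPM. Every direction below is therefore given for libraries as labelled TG against libraries as labelled WT. Pde4d (ENSMUSG00000021699), a phosphodiesterase that degrades cyclic AMP, rose 1.49-fold, from 20.1 ± 2.85 CPM to 30.0 ± 3.98 CPM (SD, n = 4 each; log2 fold change 0.58, SE 0.13, adjusted p = 0.00636). All 4 TG-labelled libraries exceeded all 4 WT-labelled libraries for Pde4d. The fold change of Atf4 was −0.47 (SE 0.185) and its adjusted p 0.305 when the mean log2 CPM of vascular and stromal genes, which also separated the groups, was a covariate. That of Pde4d was 1.13 (SE 0.25) with the covariate, with adjusted p = 0.0275.

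**Figure D1:**
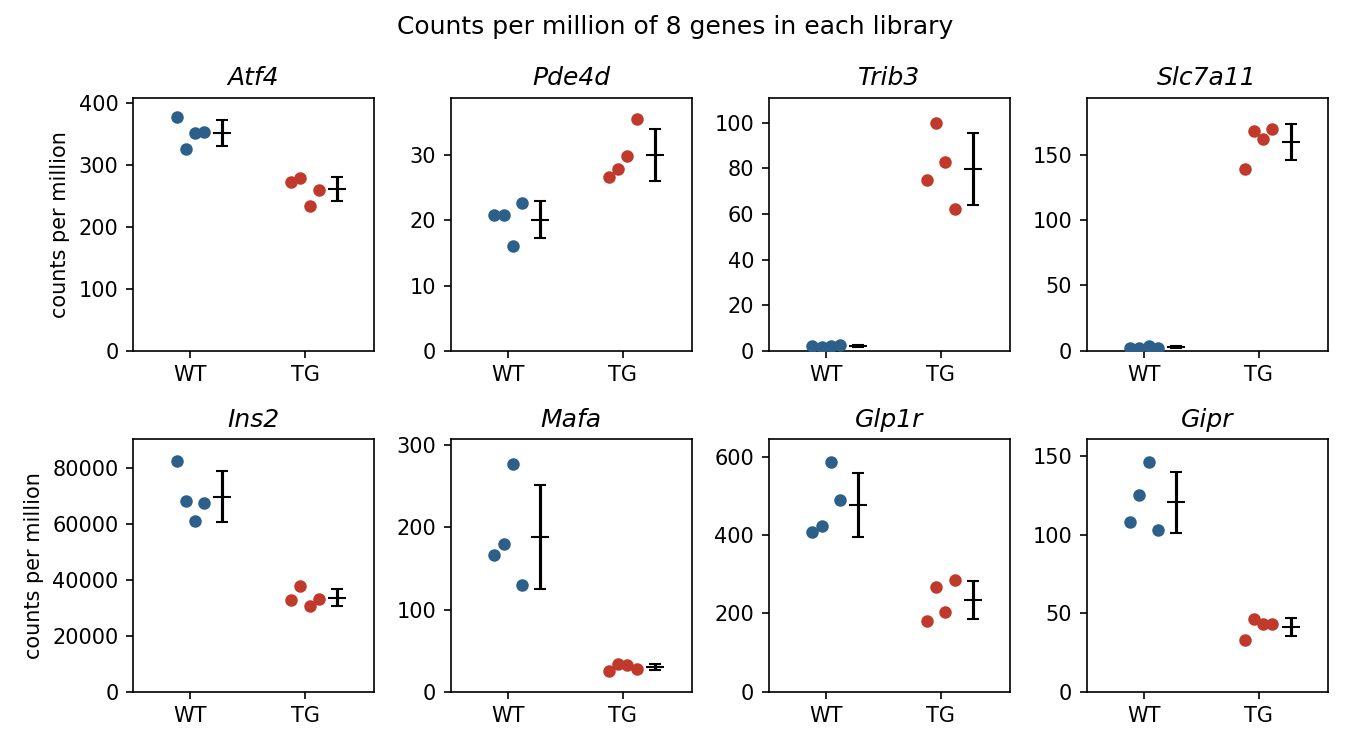
Normalised read counts (CPM) of Atf4, Pde4d, Trib3, Slc7a11, Ins2, Mafa, Glp1r and Gipr in each of the 8 libraries (points; linear vertical axes from 0), with the mean and SD of each group of 4 (black). Atf4 lay at 234 to 278 CPM in the TG-labelled libraries and at 326 to 378 CPM in the WT-labelled libraries, and in each panel the 2 groups did not overlap.

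Of 20509 genes tested, 4129 (20.1%) differed between the groups at an adjusted p under 0.05, 2475 of them higher and 1654 lower in the TG-labelled islets. A list of genes drawn at random would hold about this share of called genes. A change of at least 2-fold was found for 1614 genes (1315 higher, 299 lower). The 2 groups did not overlap for 4631 genes, 22.6% of those tested, where chance gives 2.86%. Among called genes with a mean of at least 5 CPM and no overlap between the groups, leaving out clone-based and similar symbols, the largest rise was that of Fut1, a fucosyltransferase, at 89.7 ± 8.86 CPM against 0.647 ± 0.162 CPM (log2 fold change 7.12, SE 0.16, adjusted p = 3.43e-13). The next 9 genes were Slc7a3 (log2 fold change 6.16), a carrier of cationic amino acids, Cyb5r2 (6.16), Bcat1 (6.09), a branched-chain amino acid transaminase, P2rx3 (6.02), an ATP-gated ion channel, Slc7a11 (5.98), the cystine-glutamate exchanger, Gdf15 (5.48), a secreted stress factor, Trib3 (5.39), a pseudokinase, Cth (5.21), an enzyme of cysteine synthesis, and G0s2 (5.21), an inhibitor of fat breakdown. Their adjusted p-values lay between 4.17e-12 and 1.47e-05. Over the 21 settings Cyb5r2 lay between 5.77 and 8.48, Gdf15 between 4.35 and 5.96 and G0s2 between 4.37 and 5.38, and each was called in all of them. The largest fall among such genes was that of Trpm5, a cation channel opened by calcium, from 68.2 ± 7.63 CPM to 4.45 ± 0.566 CPM (log2 fold change −3.94, SE 0.13, adjusted p = 2.05e-11). It was followed by Fam151a (−2.80), Cib3 (−2.70), T2 (−2.68), Tmem215 (−2.66), Mafa (−2.65), Slc2a2 (−2.58), Adam32 (−2.47), Msln (−2.20) and Sytl4 (−2.20). With the vascular and stromal covariate, which raised the standard error of the median gene 2.10-fold, 376 genes were called (149 higher, 227 lower), 299 of them changed at least 2-fold. Overlapping and antisense genes are uncertain here, since the strand setting of the counting is not given in the sources used here.

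Genes that supply and charge amino acids rose together with known targets of the integrated stress response. Of 26 integrated stress response targets, 19 were higher and 0 lower (22 higher adjusted over the list alone), with a median log2 fold change of 1.22. Besides Trib3 and Gdf15 these included Eif4ebp1, a translation repressor (3.16, SE 0.11), and Vldlr, a lipoprotein receptor (1.45, SE 0.12). Of 19 enzymes of amino acid synthesis and one-carbon metabolism, 13 were higher and 1 lower (14 and 1 adjusted over the list alone; median 2.40). Among them Phgdh, the first enzyme of serine synthesis, reached 253 ± 25.6 CPM against 25.1 ± 2.46 CPM, and the mitochondrial folate enzyme Aldh1l2 reached 418 ± 58.5 CPM against 31.3 ± 4.34 CPM. Of 17 amino acid transporters, 11 were higher and 1 lower (the same numbers adjusted over the list alone; median 1.22). Beside Slc7a11 and Slc7a3, Slc7a1 rose by 1.66 (SE 0.11) and Slc1a4 by 2.44 (SE 0.19) on the log2 scale. Cytosolic aminoacyl-tRNA synthetases, which load amino acids onto tRNAs, counted 13 of 20 higher and 0 lower (13 higher and 1 lower adjusted over the list alone; median 0.66). Nars (1.03), Mars (1.07), Tars (0.90) and Aars (0.88) had the lowest adjusted p-values of this group. The set test camera with a preset correlation of 0.01 gave adjusted p-values of 7.47e-17 for the stress response targets, 8.09e-14 for the synthesis enzymes, 5.45e-07 for the transporters and 1.77e-08 for the synthetases. With an estimated correlation none of the 4 lists was called, with adjusted p = 0.113, adjusted p = 0.13, adjusted p = 0.155 and adjusted p = 0.161 in this order. With the vascular and stromal covariate, 7 stress response targets, 11 synthesis enzymes, 5 transporters and 6 synthetases were called higher. The medians of these lists were 1.04, 2.15, 0.999 and 0.62, and camera called each of them. Mthfd1, the synthesis enzyme called lower (−0.74, named after its value was seen), was at −0.77 with it (adjusted p = 0.0419), and the call of Aars was lost (0.75, adjusted p = 0.121).

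Transcripts that define beta cells were lower. Of 25 beta-cell identity genes, 20 were lower and 0 higher (21 lower adjusted over the list alone), with a median log2 fold change of −0.89. Slc2a2, the glucose transporter GLUT2, stood at 137 ± 9.50 CPM against 820 ± 50.5 CPM, and Mafa, a transcription factor of the insulin gene, at 30.0 ± 3.74 CPM against 188 ± 62.7 CPM. The zinc transporter Slc30a8 fell by 1.62 (SE 0.11) on the log2 scale, and the prohormone convertase Pcsk1 stood at 525 ± 61.6 CPM against 1050 ± 53.6 CPM. Ins2 changed by −1.05 (SE 0.10, adjusted p = 5.3e-06) and Ins1 by −1.59 (SE 0.20, adjusted p = 0.0004), where reads shared by these similar genes make the split between them uncertain. Together Ins1 and Ins2 took 4.13% ± 0.427 (SD, n = 4) of gene counts in the TG-labelled libraries and 8.63% ± 0.574 (SD, n = 4) in the WT-labelled libraries, 2.09-fold lower (exact permutation test, two-sided, p = 0.0286, the smallest value that 70 arrangements allow). Of 27 genes of the secretion machinery and ion channels, 14 were lower and 2 higher (17 and 2 adjusted over the list alone; median −0.38). Sytl4, a granule docking protein, fell by 2.20 (SE 0.10), and the granule protein Chga fell by 0.81 (SE 0.15). Of 23 tested genes that are silenced in mature beta cells or mark their dedifferentiation, 15 were higher and 0 lower (16 higher adjusted over the list alone; median 0.94). Aldh1a3, an enzyme of retinoic acid synthesis, reached 91.4 ± 19.9 CPM against 4.36 ± 1.86 CPM, and Lmo4 rose by 1.55 (SE 0.23). Camera gave adjusted p-values of 2.65e-19 for the identity genes, 1.02e-07 for the secretion genes and 3.53e-10 for the dedifferentiation genes. Each call was lost with an estimated correlation (adjusted p = 0.0993, adjusted p = 0.249 and adjusted p = 0.113). With the vascular and stromal covariate, 11 identity genes and 1 secretion gene were called lower and 4 dedifferentiation genes higher, with medians of −0.83, −0.22 and 0.21, and camera called each list (adjusted p = 1.73e-18, adjusted p = 0.0239 and adjusted p = 0.000374). Calls were lost for Lmo4 (0.57, adjusted p = 0.622), Chga (−0.92, adjusted p = 0.148), Ins2 (−0.85, adjusted p = 0.0513) and Ins1 (−1.73, adjusted p = 0.0564). Among genes still called with it, Mafa stood at −3.44 (adjusted p = 2.77e-07), Slc30a8 at −1.20 (adjusted p = 0.00179) and Pcsk1 at −0.79 (adjusted p = 0.0408).

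Transcripts of the receptors for both incretin hormones were lower, as were Ins2 (−1.05) and the beta-cell identity genes (median −0.89). Receptor levels within beta cells were not measured apart from the share of beta cells. Gipr, the receptor for glucose-dependent insulinotropic polypeptide, fell from 121 ± 19.3 CPM to 41.4 ± 5.67 CPM (log2 fold change −1.54, SE 0.13, adjusted p = 9.8e-07). Glp1r, the receptor for glucagon-like peptide 1, fell from 477 ± 81.7 CPM to 234 ± 49.4 CPM (log2 fold change −1.03, SE 0.16, adjusted p = 0.00074), and with the vascular and stromal covariate its log2 fold change was −1.22 with adjusted p = 0.051. Of 26 genes of incretin receptor and cyclic AMP signalling, 6 were lower and 4 higher (7 and 4 adjusted over the list alone; median −0.11), and the list as a whole was not called (camera, adjusted p = 0.143), but it was called lower with no filter on low counts (median −0.13, adjusted p = 0.00469). Rapgef4, a cyclic AMP sensor of beta cells, changed by −0.61 (SE 0.093), while its relative Rapgef3 changed by 0.79 (SE 0.12). The adenylyl cyclases Adcy5 (0.76) and Adcy7 (1.54) and the anchoring protein Akap12 (1.09) rose. Adcy9 (−0.39), Crem (−0.47) and Pkib (−0.56) fell, but these 3 missed the threshold with acinar genes as a covariate (adjusted p = 0.109, adjusted p = 0.0823 and adjusted p = 0.0641) and without single libraries. Adcy9 was −0.30 without TG replicate 1, −0.36 without WT replicate 2 and −0.36 without WT replicate 4. Crem was −0.40 without TG replicate 2, −0.45 without TG replicate 3 and −0.38 without WT replicate 4, and Pkib was −0.47 without TG replicate 1 and −0.52 without WT replicate 1. The other 16 members, among them Gnas (−0.33, SE 0.15) and Prkaca (−0.20, SE 0.099), did not pass the test. Under other settings Gnas passed it without TG replicate 4 (−0.50, adjusted p = 0.0249) and with no filter (−0.35, adjusted p = 0.021), Adcy1 without TG replicate 4 (0.61), Prkaca with a replicate block and GC offsets (−0.26), and Prkacb and Irs2 in 5 settings each, among them without WT replicate 3 (−0.36) and without WT replicate 4 (−0.47). Gipr (−1.81, adjusted p = 0.000164) was the only member called with the vascular and stromal covariate. The log2 fold changes were then 0.12 for Adcy7, 0.14 for Akap12, 0.61 for Adcy5, 0.42 for Rapgef3 and −0.61 for Rapgef4 (adjusted p between 0.152 and 0.947), and −0.18, −0.35 and −0.41 for Adcy9, Crem and Pkib.

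Phosphodiesterases, which degrade cyclic nucleotides, went both ways. Of 19 tested, 3 were higher and 2 lower (6 and 3 adjusted over the list alone), where the share called among all tested genes would give 3.83. Besides Pde4d, Pde3a rose by 0.54 (SE 0.14) and Pde1a by 0.79 (SE 0.24). Pde1c changed by −1.18 (SE 0.12), from 48.8 ± 5.38 CPM to 21.6 ± 3.35 CPM, and Pde3b by −0.59 (SE 0.091). The call of Pde1a was lost without TG replicate 1 (0.67), without TG replicate 3 (0.75), without WT replicate 2 (0.61) and without WT replicate 4 (0.77). The other members of the PDE4 family measured −0.05 (Pde4a), −0.28 (Pde4b) and −0.30 (Pde4c), with adjusted p-values of 0.93, 0.085 and 0.34. The list as a whole was not called (camera, adjusted p = 0.879), with a median of 0.08 and a mean of 0.06 against a test direction of lower. With acinar genes as a covariate the calls of Pde3a (0.44, adjusted p = 0.0504) and Pde1a (0.65, adjusted p = 0.117) were lost. Pde3a and Pde1a, with the vascular and stromal covariate, stood at −0.09 and −0.02, and the call of Pde3b was lost (−0.65, adjusted p = 0.119).

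Cell proliferation genes were lower, and so were 6 of 24 cholesterol synthesis genes. Genes of the endoplasmic reticulum went both ways. Of 31 endoplasmic reticulum chaperones and degradation genes, 3 were higher and 3 lower (3 and 5 adjusted over the list alone; median −0.10; camera, adjusted p = 0.213). The share called among all tested genes would give 6.24 of 31. The list was called lower without WT replicate 2 (median −0.16, adjusted p = 0.0396) and with no filter on low counts (median −0.13, adjusted p = 0.00176). The oxidase Ero1lb changed by −1.83 (SE 0.11) and its relative Ero1l by 1.03 (SE 0.10), and Sel1l and Herpud1, parts of the degradation machinery, rose by 0.86 and 0.77. Cell proliferation genes counted 17 of 29 lower and 0 higher (18 lower adjusted over the list alone; median −0.86; camera, adjusted p = 8.01e-11, and adjusted p = 0.161 with an estimated correlation). Mki67 stood at 67.7 ± 4.52 CPM against 158 ± 34.0 CPM, and Top2a at 46.1 ± 9.85 CPM against 121 ± 21.1 CPM. Of 24 cholesterol synthesis genes, 6 were lower and 0 higher (7 lower adjusted over the list alone; median −0.28; camera, adjusted p = 1.84e-05, and adjusted p = 0.167 with an estimated correlation). The share called among all tested genes, in either direction, would give 4.83 of 24. Oxidative stress response genes counted 10 of 21 higher and 0 lower (11 higher adjusted over the list alone; median 0.30; camera, adjusted p = 0.000248, and adjusted p = 0.161 with an estimated correlation), among them Hmox1 (1.89), Cat (1.36) and Gstm1 (1.07). Apoptosis genes counted 8 of 21 higher and 0 lower (8 adjusted over the list alone; median 0.21; camera, adjusted p = 0.00268, and adjusted p = 0.194 with an estimated correlation). Txnip, which had the lowest adjusted p of them, stood at 1514 ± 136 CPM against 705 ± 95.7 CPM. Hypoxia and glycolysis genes counted 6 of 20 higher and 2 lower (8 and 2 adjusted over the list alone; median 0.27; camera, adjusted p = 0.00715, and adjusted p = 0.256 with an estimated correlation), with Pfkfb3 at 1.56 and Ankrd37 at −0.81. Of 38 nuclear genes of oxidative phosphorylation, 0 were higher and 1 was lower (the same numbers adjusted over the list alone), with a median of 0.02, a mean of −0.02 and a test direction of lower (camera, adjusted p = 0.53). Of 9 mitochondrially encoded mRNAs, 1, mt-Co1 (−0.51), was lower and 0 higher (the same numbers adjusted over the list alone; median −0.60; camera, adjusted p = 0.00656, and adjusted p = 0.335 with an estimated correlation). With the vascular and stromal covariate, 9 proliferation genes and 4 cholesterol genes were called lower, with medians of −1.37 and −0.41, and camera called both lists. With it edgeR called 0 genes of the oxidative stress, apoptosis and hypoxia lists, where 4, 1 and 4 had an unadjusted p under 0.05. Camera still called the oxidative stress list (median 0.14, adjusted p = 0.0117) but not the apoptosis (−0.05, adjusted p = 0.381) and hypoxia lists (0.07, adjusted p = 0.631). The log2 fold changes were then 1.80 for Hmox1, 0.63 for Cat, 0.84 for Gstm1, 0.79 for Txnip, 1.29 for Pfkfb3 and −0.83 for Ankrd37. The mitochondrially encoded list was not called with it (median −0.06, adjusted p = 0.381) nor by fry (adjusted p = 0.0817), and calls were lost for mt-Co1 (−0.71, adjusted p = 0.0673), Sel1l (0.36, adjusted p = 0.564) and Herpud1 (0.81, adjusted p = 0.211). In the endoplasmic reticulum list 1 gene was then called higher and 3 lower.

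**Figure D2:**
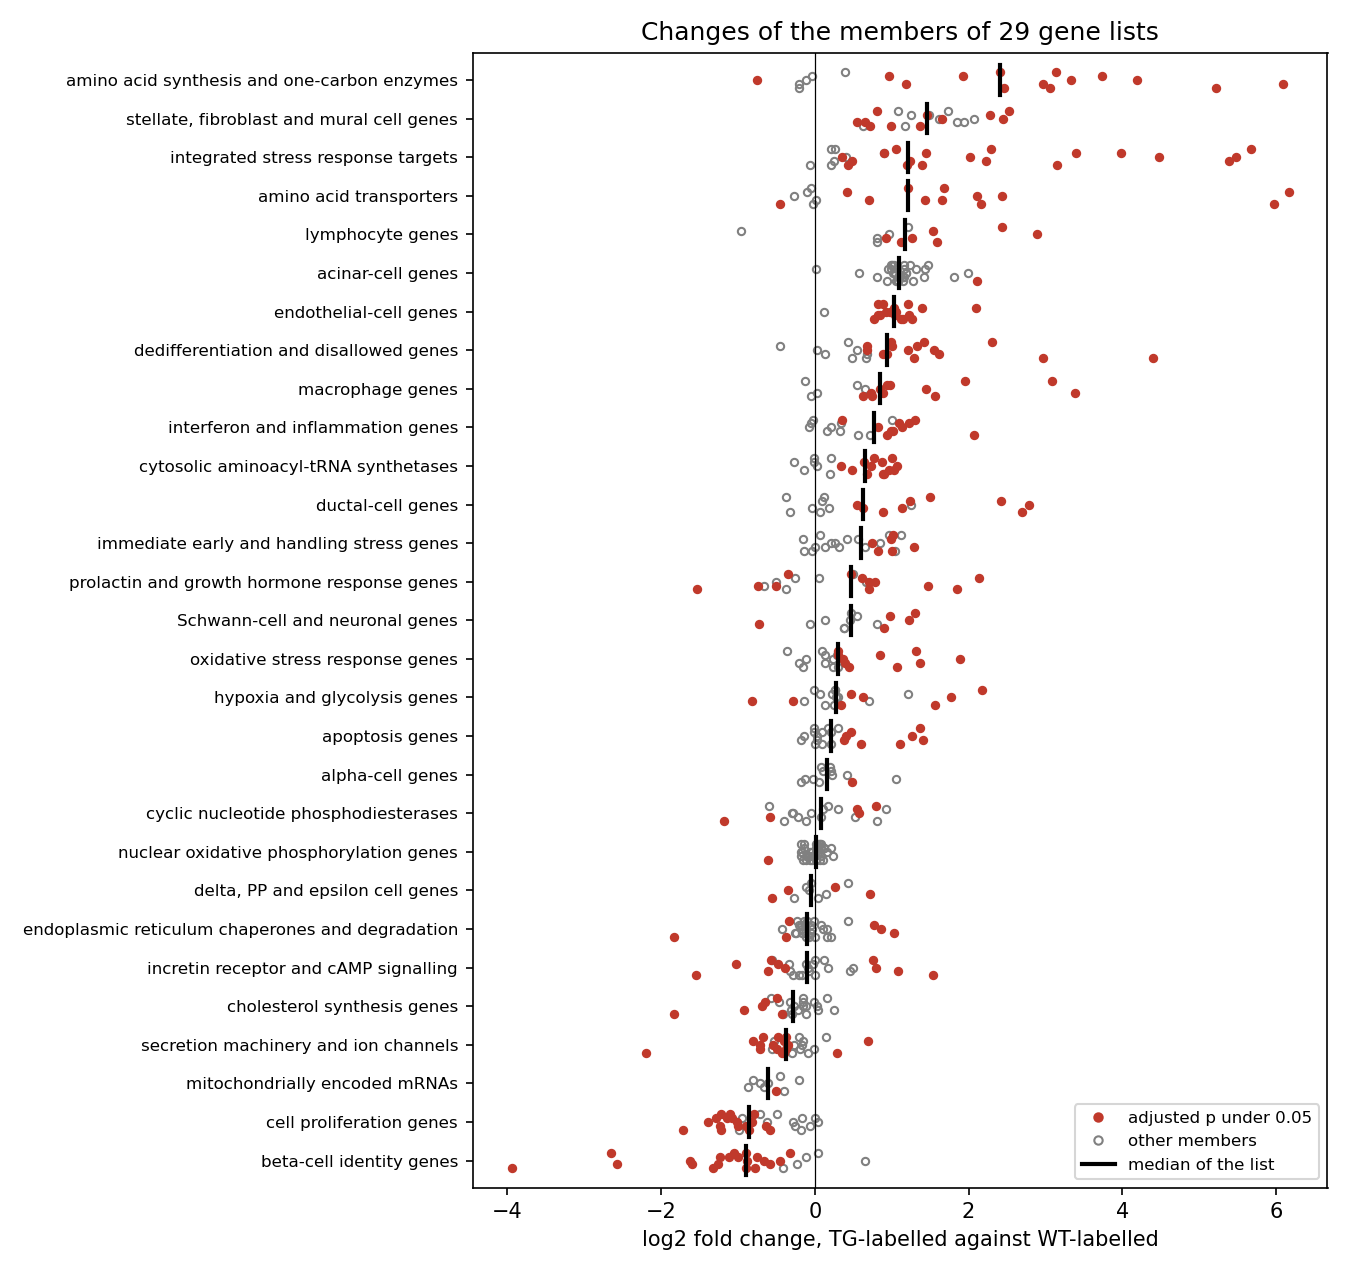
Log2 fold change (TG-labelled against WT-labelled, horizontal axis) of every tested member of 29 gene lists fixed beforehand, with members past an adjusted p of 0.05 in red, the others as open circles and the median of each list as a black bar. Medians run from −0.89 for beta-cell identity genes to 2.40 for enzymes of amino acid synthesis and one-carbon metabolism.

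Markers of vascular and connective tissue cells were higher in the same libraries. Of 18 endothelial-cell genes, 17 were higher and 0 lower (17 adjusted over the list alone; median 1.03; camera, adjusted p = 1.42e-12, and adjusted p = 0.161 with an estimated correlation). Egfl7 stood at 118 ± 13.9 CPM against 54.4 ± 11.0 CPM and Emcn at 147 ± 9.27 CPM against 83.3 ± 13.2 CPM. Of 21 genes of stellate cells, fibroblasts and mural cells, 11 were higher and 0 lower (18 higher adjusted over the list alone; median 1.46; camera, adjusted p = 2.17e-12, and adjusted p = 0.179 with an estimated correlation), among them Thy1 (1.36, SE 0.19) and Rgs5 (0.65, SE 0.12). The mean log2 CPM of these 2 lists was 6.24 ± 0.160 (SD, n = 4) in the TG-labelled libraries and 4.93 ± 0.541 (SD, n = 4) in the WT-labelled libraries, with no library of the first group below 6.09 and none of the second above 5.70 (exact permutation test, two-sided, p = 0.0286, the smallest value possible). Macrophage genes counted 12 of 17 higher and 0 lower (12 adjusted over the list alone; median 0.85; camera, adjusted p = 9.25e-06, and adjusted p = 0.228 with an estimated correlation), with Adgre1 at 1.45 and Csf1r at 0.94. Lymphocyte genes counted 7 of 12 higher and 0 lower (7 adjusted over the list alone; median 1.17; camera, adjusted p = 0.000633, and adjusted p = 0.161 with an estimated correlation), with Ptprc at 1.13 and Coro1a at 1.27. Interferon and inflammation genes counted 10 of 20 higher and 0 lower (11 higher adjusted over the list alone; median 0.77; camera, adjusted p = 4.94e-05, and adjusted p = 0.291 with an estimated correlation), with Icam1 at 2.07 and Ifit2 at 0.99. Immediate early and handling stress genes counted 6 of 22 higher and 0 lower (8 higher adjusted over the list alone; median 0.61; camera, adjusted p = 0.000234, and adjusted p = 0.313 with an estimated correlation), with Klf4 at 1.01 and Ier3 at 1.29. With the vascular and stromal covariate, the mean of the first 2 of these lists, edgeR called 0 genes of the endothelial, macrophage, lymphocyte, interferon and immediate early lists, of which 1, 0, 0, 2 and 4 had an unadjusted p under 0.05, and the calls of Thy1 (0.53) and Rgs5 (0.04) were lost. In the stellate, fibroblast and mural list edgeR then called 0 genes higher and 1 lower, and 6 had an unadjusted p under 0.05.

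Markers of other cells of the pancreas did not move as a block. Alpha-cell genes counted 1 of 12 higher and 0 lower (the same numbers adjusted over the list alone; median 0.16; camera, adjusted p = 0.283). The list was called higher without WT replicate 1 (median 0.26, adjusted p = 0.0448) and with the vascular and stromal covariate (median 0.28, adjusted p = 0.0239). Gcg, the glucagon gene, measured 33851 ± 8360 CPM against 25332 ± 6827 CPM (log2 fold change 0.42, adjusted p = 0.26). Genes of delta, PP and epsilon cells counted 2 of 11 higher and 2 lower (the same numbers adjusted over the list alone), with a median of −0.04, a mean of 0.02 and a test direction of lower (camera, adjusted p = 0.85), and Sst (−0.08) and Ppy (0.14) did not pass the test. Ductal-cell genes counted 9 of 17 higher and 0 lower (9 and 1 adjusted over the list alone; median 0.62; camera, adjusted p = 0.000609, and adjusted p = 0.256 with an estimated correlation), with Spp1, a secreted phosphoprotein, at 501 ± 126 CPM against 77.2 ± 21.5 CPM. Schwann-cell and neuronal genes counted 4 of 13 higher and 1 lower (5 and 1 adjusted over the list alone; median 0.47; camera, adjusted p = 0.00709, and adjusted p = 0.313 with an estimated correlation), with Cdh19 at 0.89. Of 10 adipocyte genes only 2 were expressed enough to test, and both, Fabp4 (1.85) and Plin4 (1.28), were higher (2 adjusted over the list alone). Acinar-cell genes counted 1 of 34 higher and 0 lower (0 adjusted over the list alone; median 1.10; camera, adjusted p = 0.000234, and adjusted p = 0.536 with an estimated correlation), and fry did not call the list (adjusted p = 0.288). They took 2.82% ± 2.50 of counts in the TG-labelled libraries and 1.22% ± 0.805 in the WT-labelled libraries (SD, n = 4 each; exact permutation test on log2 shares, two-sided, p = 0.257), a 2.44-fold difference of mean log2 shares that was 1.49-fold without WT replicate 4. The single call was that of Prss1 (2.11), a trypsinogen that shares reads with its paralogs, and it was lost without TG replicate 1 (0.88, adjusted p = 0.31), without each WT replicate in turn (2.07, 2.05, 2.13 and 2.14), by limma-voom (1.45), with a replicate block (1.57) and with acinar genes as a covariate (1.05). After the vascular and stromal covariate was added, the ductal list (median 0.12, adjusted p = 0.207) and the Schwann-cell list (median −0.12, adjusted p = 0.712) were not called, and Spp1 stood at 1.67 (adjusted p = 0.00433). Camera at the preset correlation then called the acinar list lower (median −1.49, adjusted p = 0.000109). But edgeR called 0 of its 34 genes, and 0 had an unadjusted p under 0.05. The estimated correlation of this list, without the covariate, was 0.856, so its camera call is not evidence of fewer acinar transcripts. The calls of Fabp4 (0.83, adjusted p = 0.12) and Plin4 (0.47, adjusted p = 0.871) were lost, the latter also with acinar genes as a covariate (1.17, adjusted p = 0.0573).

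**Figure D3:**
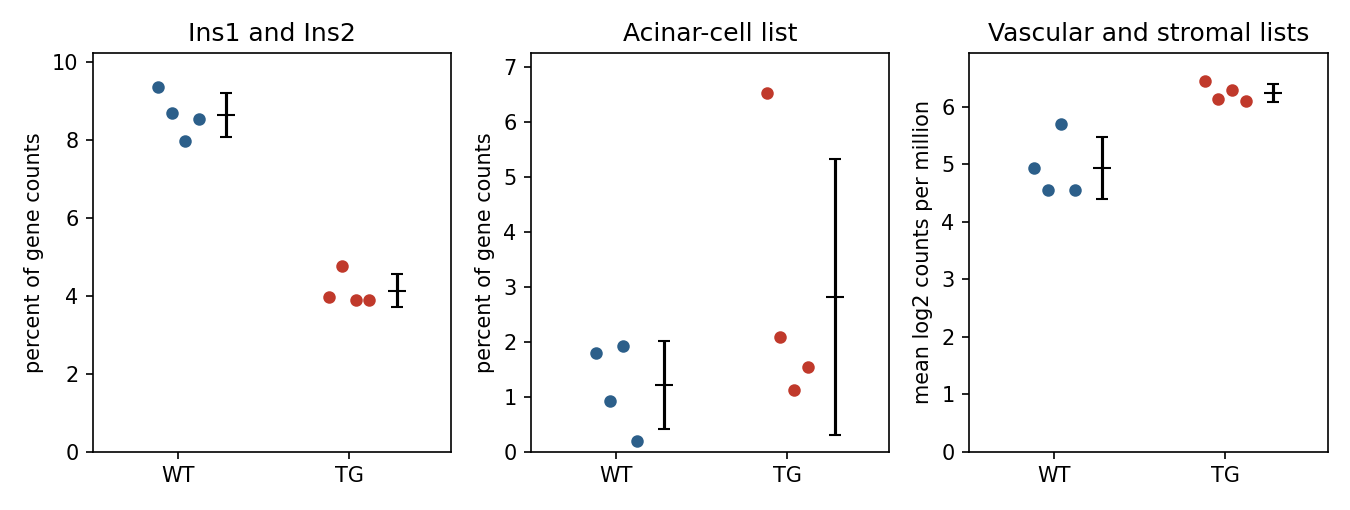
Share of gene counts from Ins1 and Ins2 (left, percent), share from the acinar-cell list (middle, percent) and mean log2 CPM of the endothelial and the stellate, fibroblast and mural lists (right) in each library (points), with the mean and SD of each group of 4 (black). The insulin share averaged 4.13% in TG-labelled and 8.63% in WT-labelled libraries, the acinar shares overlapped, and the vascular and stromal means did not overlap.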

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

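Both tests on Atf4, the comparison of endothelial with other endocrine genes and the restriction to weakly expressed receptor genes were chosen only after the result was seen.

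Atf4 was lower in the libraries labelled TG (log2 fold change −0.43), while the labels give both groups an ATF4 transgene and only that group the Cre driver. An exchange of the labels between the groups was argued against by the targets of the integrated stress response, of which 19 were called and 100% were higher in the TG-labelled libraries. Transcripts of the transgene that are not counted under Atf4 stay open, because the transgene's sequence was not analysed here and the tables hold no value for it. A biological effect of the driver on endogenous Atf4 mRNA may also account for −0.43 and was not tested.

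Insulin and beta-cell identity genes were lower in the TG-labelled libraries. Ins2 stood at −1.05 (adjusted p = 4.14e-06, edgeR) with the 50 most abundant genes left out of the scaling and at −1.08 (adjusted p = 3.30e-05, edgeR) with acinar genes as a covariate, so neither a few abundant genes nor exocrine tissue accounts for the whole fall. For a smaller share of beta cells, the planned test left the explanation standing: the other 23 identity genes had a median of −0.88 (bootstrap SE over genes 0.146), within 2 SE of Ins2 at −1.05. A smaller share would raise markers of all other cells alike. Yet the endothelial median exceeded that of 23 alpha, delta, PP and epsilon cell genes (0.08) by 0.95. The 95% bootstrap interval of 0.734 to 1.15 came from drawing genes, not libraries, so it holds no spread between libraries. Endothelial genes also moved together (estimated correlation 0.586). Within these limits, the difference argues against a smaller share as the whole cause. More vascular and stromal cells alone would lower genes of all endocrine cells alike, while the alpha, delta, PP and epsilon median was 0.08. Both changes together could offset each other in these genes, so this median does not argue against the combination. The 23 identity genes ran from −3.94 to 0.65, where cell shares alone would move genes made only by beta cells alike. This range argues against cell shares as the whole cause for the genes that fell most, which are the extremes of the list. Lower expression within beta cells was not measured apart from cell shares, and both may contribute.

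TG replicates 1, 2 and 3 had 39510, 38252 and 38017 genes with at least 1 count, against 31088 to 34189 in the other 5 libraries. Depth is argued against, since after thinning to equal totals these 3 still had at least 37053 such genes and the others at most 34189. Reads from DNA or other sources spread over the genome may be a cause: olfactory and vomeronasal receptor genes took at least 0.0592% of counts in the 3 libraries (TG replicate 3, Wilson interval 0.0581 to 0.0602) and at most 0.0581% in the others (WT replicate 4, 0.0570 to 0.0593), and over 1924 weakly expressed receptor genes 0.05003% (0.0491 to 0.0510) and 0.0479% (0.0469 to 0.0490). The planned criterion, each of the 3 above each of the other 5, was thus met by a narrow margin, while WT replicate 4 had 34189 genes with a count after thinning and TG replicate 3 had 37117. Reads outside any gene made up 31.5%, 25.5% and 27.2% of the totals in TG replicates 1, 2 and 3. In the other libraries they made up 25.3% to 29.5%, so only TG replicate 1 stood above them. The explanation by DNA or other sources stays open, and no biological explanation was tested.

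In 20 of 360 groups of 4 values a single library lay far from the other 3, where chance gives about 18. In TG replicate 1 these were Slc7a3 at 80.2 CPM (nearest other value 121.5), Prss1 at 6.69 CPM (1.25), Try5 at 1204 CPM (364), Plin4 at 5.56 CPM (3.66) and Pde8a at 47.6 CPM (61.3). In TG replicate 2 they were Eif4ebp1 at 121.8 CPM (109.04), Creb1 at 120.5 CPM (141.05) and the insulin share of 4.77% (Wilson interval 4.76 to 4.78, nearest 3.96). TG replicate 4 stood apart for Lmo4 at 12.6 CPM (18.5), Oasl2 at 10.7 CPM (13.0), Pde10a at 36.9 CPM (26.7) and Prkar1a at 864 CPM (778). WT replicate 1 did for Slc7a3 at 2.995 CPM (1.22) and Spock3 at 37.4 CPM (26.4), and WT replicate 3 for Matn2 at 77.2 CPM (59.9) and Cacna1c at 80.7 CPM (85.2). WT replicate 4 did for Cth at 1.34 CPM (1.47), Nars at 263 CPM (208), mt-Nd1 at 3980 CPM (1557) and its 16521087 gene counts (21971653).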

How the results depend on the processing

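The vascular and stromal covariate was chosen only after the result was seen, and all other alternatives were planned. With it 376 genes were called (149 higher, 227 lower), 299 of them changed at least 2-fold, and 12 lists were called. Of the 376, 349 were also called without it. Atf4 was −0.47 with adjusted p = 0.305 (edgeR), an estimate close to −0.43 whose SE rose from 0.085 to 0.185. The covariate nearly follows the groups, which raised the SE of the median gene 2.10-fold. Among calls it reversed the medians of the acinar (−1.49), apoptosis (−0.053), immediate early (−0.24), interferon (−0.10), Schwann-cell (−0.12) and stellate, fibroblast and mural lists (−0.24), the last made from its own genes, and Pde3a (−0.090) and Pde1a (−0.017). Among values not called it reversed Gm5771 (−0.57), Try5 (−1.11), mt-Nd1 (0.34), Ddx3y (0.10), Uty (0.18), Pde9a (−0.12), Pde5a (0.37), Pde10a (0.20), Pde2a (−2.20), Prkacb (0.20) and the phosphodiesterase (−0.088), delta, PP and epsilon cell (0.013) and nuclear oxidative phosphorylation lists (−0.045). The acinar covariate reversed the acinar list (−0.094), from whose genes it is made. Nuclear oxidative phosphorylation, near 0, also turned with it (−0.046), upper-quartile factors (−0.022), no filter (−0.0030), GC offsets (−0.050) and these with the replicate block (−0.049). Creb1 and Adcy8 turned to 0.0032 and 0.0047 with the 50 most abundant genes left out of the scaling and to 0.013 and 0.014 with the stricter filter. With an estimated correlation camera called 0 of 29 lists, with 8 at an unadjusted p under 0.05, against 22 with the preset correlation and 20 with fry. The cause of the other changes was not tested.

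With 1 library left out, 2864 to 4404 genes were called (higher 1691 to 2622, lower 1122 to 2131, at least 2-fold 1213 to 1924) and 22 to 23 lists. Atf4 lay between −0.47 and −0.40, Pde4d between 0.45 and 0.63, the log2 insulin share between −1.14 and −1.02 and the log2 acinar share between 0.58 and 1.65. Values not called that turned there were Pde6d (−0.062 to 0.21), Pde4a (−0.20 to 0.11), Pde2a (−0.32 to 1.063), Nr4a1 (−0.34 to 0.0033), Creb1 (−0.060 to 0.053), Adcy8 (−0.17 to 0.14) and the phosphodiesterase (−0.14 to 0.13), delta, PP and epsilon cell (−0.15 to 0.12) and nuclear oxidative phosphorylation lists (−0.030 to 0.044). Other planned settings called 2979 genes (acinar covariate) to 5012. The replicate numbers were not used as pairs: correlations of deviations were −0.03, 0.08, 0.02 and 0.01, and only for number 2 was the own number best. A replicate block called 4673 genes, and 5012 with GC offsets, with Atf4 at −0.43 and −0.50, Pde4d at 0.58 and 0.53, and 22 lists in each. Without a filter the median of all genes moved to 0.11. Of 3377 values for 169 named genes, 3161 kept direction and side of the threshold, 141 lost it, 48 gained it and 27 reversed, 2 of them for called genes. Of 638 list values these numbers were 575, 30, 5 and 28, with 7 for called lists. Xist as a covariate was not run, since Xist was low and Ddx3y high in every library. On simulated data with 200 changed genes, 22.1% of genes changed 1.5-fold were recovered. In the real data 4129 genes were called, and the adjusted threshold loosens as more genes change, so this share may not hold there.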

Other observations

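The bootstrap of the neighbour difference, the leaving out of neighbours that were themselves induced, the test of prolactin response genes and the single genes named here outside the rule were chosen only after the result was seen.

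Cd5l, Marco, Alox15 and Saa3 stood apart in TG replicates 2 and 3. Cd5l, a protein secreted by macrophages, stood at 14.5 and 11.5 CPM there and at no more than 1.24 CPM in the other 6 libraries. Marco, a scavenger receptor, measured 8.18 and 11.3 CPM against at most 0.702 CPM. Alox15, a lipoxygenase, measured 14.5 and 20.7 CPM against at most 1.34 CPM, and Saa3, an acute-phase protein, 18.5 and 14.0 CPM against at most 0.417 CPM. The olfactory receptor gene Olfr649 was at 0.309 CPM in TG replicate 3 and 0 in WT replicate 2, and at 18.8 to 36.7 CPM in the other 6 libraries. Olfr330 had between 4.04 and 7.06 CPM in the TG-labelled libraries and 0 counts in each WT-labelled library.

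The real grouping gave 4129 called genes, and of the 35 splits of the 8 libraries into 4 and 4 only 1, the real one, gave as many. The highest of the other splits was 0 (edgeR), and at an unadjusted p under 0.05 the real split had 6523 genes and the highest other 2788. At the level that 35 splits allow, this argues against a random assignment of these libraries to groups. It cannot exclude differences between animals or preparations, since the labels do not say whether the samples came from separate animals. The other splits mix the groups, so their spread holds the difference between the groups.

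Some genes next to strongly induced genes were higher as well. Izumo1 and Fgf21, on either side of Fut1, stood at 3.29 to 5.75 and 7.77 to 12.7 CPM in the TG-labelled libraries and at most at 0.145 and 0.628 CPM in the others. Fgf21 is itself a member of the gene lists fixed beforehand, so its rise need not come from Fut1. A hypothesis is that reads running past the end of an induced gene are counted in the next gene. Next to 61 induced genes, only neighbours that passed the filter on low counts were used. A gene can pass it through its counts in the TG-labelled libraries alone, which favours neighbours that are higher there. Of these neighbours, 2 downstream and 5 upstream were induced genes themselves and were left out, which can also remove genes raised by read-through. Of the other 22 downstream neighbours 7 were called higher (31.8%), and of the other 25 upstream neighbours 3 (12%), against 11.8% of all genes that were not induced. The downstream median was 0.36, above 99.4% of 10000 random sets of matched expression, and the upstream median was 0.16, above 92.5%. The difference of 0.20 had a 95% bootstrap interval over genes from −0.195 to 1.11, so read-through cannot be told apart from neighbours that may change on their own.

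Some insulin-promoter Cre lines carry a growth hormone sequence, and a hypothesis is that such a sequence may act in these islets. Of 19 tested prolactin and growth hormone response genes, 8 were higher and 4 lower (the same numbers adjusted over the list alone), with a median of 0.48 and camera adjusted p = 0.403. Cldn8 rose by 2.13 (2.76 without WT replicate 3) and Matn2 by 0.70, while the prolactin receptor gene Prlr changed by −1.53 and Ivd by −0.74. The calls of Cldn8 (0.26, adjusted p = 0.923), Matn2 (0.18, adjusted p = 0.856) and Ivd (−0.74, adjusted p = 0.102) were lost with the vascular and stromal covariate. Tph1, a serotonin synthesis enzyme, was near the detection limit with 0.348 ± 0.259 CPM against 0.569 ± 0.328 CPM. These values leave the hypothesis open.

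Of 5 tested sex-linked genes, 0 were higher and 1, Eif2s3y (−0.48), was lower (2 lower adjusted over the list alone), and its call was lost with the vascular and stromal covariate (−0.25, adjusted p = 0.724). The share of counts on the 10 most abundant genes was 14.5% ± 1.18 in the TG-labelled and 19.8% ± 1.68 in the WT-labelled libraries (SD, n = 4 each).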
